A study of Pseudomonas aeruginosa PAO1 with 2 samples.

How the data were processed

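Total RNA of Pseudomonas aeruginosa PAO1 was measured on 2 Affymetrix arrays, 1 of suspended cells and 1 of biofilm cells, each collected after 20 hours. Per the labels' protocols, RNA was extracted with an RNeasy kit and biotin-labelled by the standard Affymetrix protocol. The deposited values are intensities on a linear scale, 1 per probe set and array. The software that summarised probes into probe sets, its background correction and the detection calls are not given in the sources used here. Each array's mean between its 2nd and 98th percentile was close to the other's, 499.8 in the suspended array and 499.98 in the biofilm array, so the deposited intensities behave as if each array had been scaled to a common trimmed mean. Such a scaling sets the bulk of the signals to a common level, so an overall difference in RNA amount between the groups cannot be read from these values. It does not make the total signal equal, since the brightest probe sets lie outside the trimmed range and differed, with rRNA medians of 67938 and 34128.

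The 5896 probe sets were split by their identifiers into 5545 for PAO1 genes, 199 for intergenic regions, 117 for genes of other strains, 18 for tRNA, 3 for rRNA and 14 controls. Gene names were taken from the locus tag in each identifier, looked up in a reference gene table of the PAO1 assembly ASM676v1, which held 5504 of the 5545 tags. The other 41 kept the name in the identifier. A platform annotation table gave 1 symbol for 5500 probe sets, several for 0 and none for 396. No genome coordinates are printed, because the build behind the array was not stated.

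Before the data were examined, the groups, the comparison, 39 gene lists, the rule for naming genes and all alternatives except 3 were fixed. Each array was rescaled to the same median over PAO1 probe sets. A floor was set at the 25th percentile of rescaled PAO1 signals over both arrays, which came to 289.3. The log2 ratio of biofilm over suspended was then taken. Genes above the floor in both arrays numbered 3707 and were counted, ranked and used in lists. A gene above it in 1 array has only a bound, and a gene below it in both was treated as not measured. The floor is a working limit, not a detection call. With 1 array per group there is no measure of spread between cultures or arrays, so no p-values were computed and differences are described by size only. The number of arrays, not the depth of measurement, limits the precision.

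For each list, the median log2 ratio of its measured members was set against 10000 random lists of the same size, drawn from the same deciles of mean log2 signal. A list is said to stand apart where its median lay outside the central 95% of these. This percentile describes these 2 arrays and is not a p-value. Lists with fewer than 3 measured members got no percentile. Named genes are the 10 with the largest and the 10 with the smallest ratios, the next 5 in each direction that carry a symbol, up to 3 members of each list with the largest absolute ratio, and the 3 largest bounds in each direction. Further members of lists that stood apart are given as examples and were chosen after their values were seen. Probe sets of the phz1 and phz2 operons, which are near-identical copies, are uncertain, and 7 of the 16 phenazine list members had no probe set under their locus tag.

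The alternatives were the values as deposited, quantile normalization, loess centring of the ratio on mean signal with a span of 0.3, a trimmed-mean scaling, a median without ribosomal protein genes, floors at the 10th and 50th percentile, at the 95th percentile of other-strain probe sets and none, a pseudocount of 0.5 of the floor with no floor, a 4-fold threshold, random lists not matched on signal, and random lists that keep neighbouring loci together (every shift of the list along the locus order). The random lists that keep neighbouring loci together were not matched on signal either. Loci not measured in both arrays were left out of them. They therefore often held fewer genes than the list itself, which widens the spread of their medians. Subtraction of each array's median intergenic intensity was added after seeing the data, as were loess centring combined with random lists that keep neighbouring loci together and the 4-fold threshold combined with other scalings. The procedure was tested on simulated data, a pair of arrays made from the levels of the suspended array over 5545 genes with known changes in bright genes. It counted as 2-fold higher or lower 95 of 95 genes planted 4-fold higher, 86 of 86 planted 4-fold lower and 2 of 3662 unchanged ones. A list shifted as a whole, the ribosomal proteins, stood apart, and so did 4 of the 38 lists that had not been shifted. This shows that planted changes are found, not how large the real error of these arrays is. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.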

Results

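Transcript levels of Pseudomonas aeruginosa PAO1, a motile Gram-negative bacterium much used as a model of biofilm growth, were compared between cells growing in suspension in a reverse osmosis unit and cells attached to the membrane of that unit. Reverse osmosis membranes remove salts from water under pressure, and attached bacterial growth on them is called biofouling. The medium was a defined one made to resemble treated wastewater, and both kinds of cells were collected after 20 hours. The data comprise 1 array per group, so no value below has a replicate error and no test between groups was possible. Values are single measurements in arbitrary signal units as deposited, and log2 ratios and folds of biofilm over suspended cells were computed after rescaling both arrays to the same median.

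The biofilm array covered a narrower range of signals than the suspended array. Among the 5545 PAO1 probe sets the median deposited signal was 356.1 in suspended cells and 449.4 in biofilm cells. The 95th percentile was 12.3 times the 5th percentile in suspended cells and 5.35 times in biofilm cells. Log2 signals of the 2 arrays correlated across genes with Pearson's r = 0.86, although genes are not independent replicates. Probe sets for genes of other strains, which PAO1 should lack, had medians of 9.30 and 5.91. A signal above their 95th percentile was seen in both arrays for 5536 of the PAO1 probe sets.

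**Figure D1:**
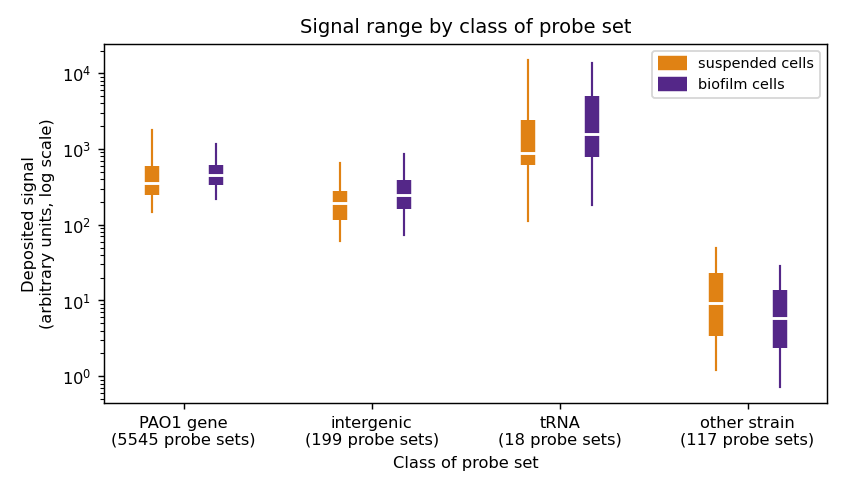
Deposited signal (arbitrary units, log scale) by class of probe set in suspended and biofilm cells; thick bars span the 25th to 75th percentile, thin lines the 5th to 95th, and white lines mark medians. PAO1 genes had medians of 356.1 and 449.4 with a narrower spread in biofilm cells, and other-strain genes had medians of 9.30 and 5.91.

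Which genes differed between attached and suspended cells was examined first by size. Of 3707 PAO1 genes above the signal floor in both arrays, 11 were at least 2-fold higher in biofilm cells and 422 at least 2-fold lower. On these rescaled values 0 were at least 4-fold higher and 63 at least 4-fold lower, against 2 and 36 as deposited, 2 and 11 with loess centring and 3 and 14 with quantile normalization, the higher ones being PA4352 and PA3309 and, with quantile normalization, adhA. The largest increase was in PA4352 (3.96-fold, from 392.2 to 1960), followed by PA3309 (3.57-fold), both encoding universal stress proteins. The fermentative alcohol dehydrogenase gene adhA (PA5427) was 3.39-fold higher, and PA1673, which encodes a hemerythrin-like oxygen-binding protein, was 2.78-fold higher. PA5027, another universal stress protein gene, was 2.57-fold higher. PA0200 (2.46-fold), PA0141 (2.40-fold, a polyphosphate kinase gene), PA1746 (2.37-fold), the pyrimidine synthesis gene pyrF (PA2876, 2.23-fold) and PA4577 (2.20-fold) completed the 10 largest. The next genes with a symbol were phzE2 (1.74-fold, uncertain because its operon has a near-identical copy), nirM (1.73-fold), algK (1.73-fold), oprG (1.70-fold) and ccoP2 (1.70-fold), all under 2-fold on the rescaled values. Of these 5, 2 were at least 2-fold higher with loess centring and 4 with quantile normalization.

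The lower genes were led by PA3691 (14.3-fold lower, from 11222 to 988.9) and its neighbour lptF (PA3692, 10.9-fold lower), which encodes an outer membrane protein. Flagellar rod and hook genes made up 5 of the 10 lowest, with flgE at 12.0-fold, flgG at 10.9-fold, flgB at 10.5-fold, flgC at 9.43-fold and flgF at 7.84-fold lower. The others were PA3819 (9.06-fold lower), PA1323 (8.18-fold lower) and PA2433 (7.57-fold lower). The lipase gene lipA was 7.50-fold lower, flgD 7.32-fold, the osmotically inducible lipoprotein gene osmE 7.19-fold, csaA 6.43-fold and flgK 6.40-fold. These folds depend on the scaling: the 10 lowest genes ran from -3.84 to -2.92 in log2 ratio on the rescaled values and from -2.54 to -1.76 with loess centring, under which PA3691 was at -2.54, lptF at -2.32, flgE at -2.20 and lipA at -1.37. All 10 were at least 2-fold lower with loess centring and with quantile normalization. Genes above the floor in suspended cells and below it in biofilm cells included sdsA1 (PA0740, an alkyl sulfatase), pilA (PA4525, the type IV pilus major subunit) and PA2815. Their log2 ratios against the floor, which are bounds, were -3.87, -3.46 and -2.85, so that sdsA1 was at least 14.6-fold and PA2815 at least 7.23-fold lower. With loess centring these bounds were -3.14, -2.83 and -2.37. In the other direction, PA5475 was at least 2.72-fold, the cytochrome c peroxidase gene ccpR at least 2.11-fold and PA0466 at least 2.06-fold higher in biofilm cells.

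The excess of lower genes went with the signal level. In the decile of measured genes with the lowest mean signal the median log2 ratio was 0.06, with 0 genes 2-fold apart in either direction. That 0 is set by the floor, since genes this close above it in both arrays cannot be 2-fold apart. In the 5th decile the median was -0.09, with 11 genes 2-fold lower and 5 higher. In the decile with the highest mean signal it was -1.09, with 209 lower and 0 higher. The share of higher genes among all genes 2-fold apart was 2.54% on the rescaled values, 13.9% on the values as deposited, 14.1% with a trimmed-mean scaling, 26.5% with loess centring and 35.9% after quantile normalization. The deposited and the trimmed-mean scales shift the median gene's log2 ratio by 0.34 against the rescaled values. Loess centring counted 39 genes as higher and 108 as lower, and these included all 11 of the higher genes and 106 of the lower genes counted on the rescaled values.

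**Figure D2:**
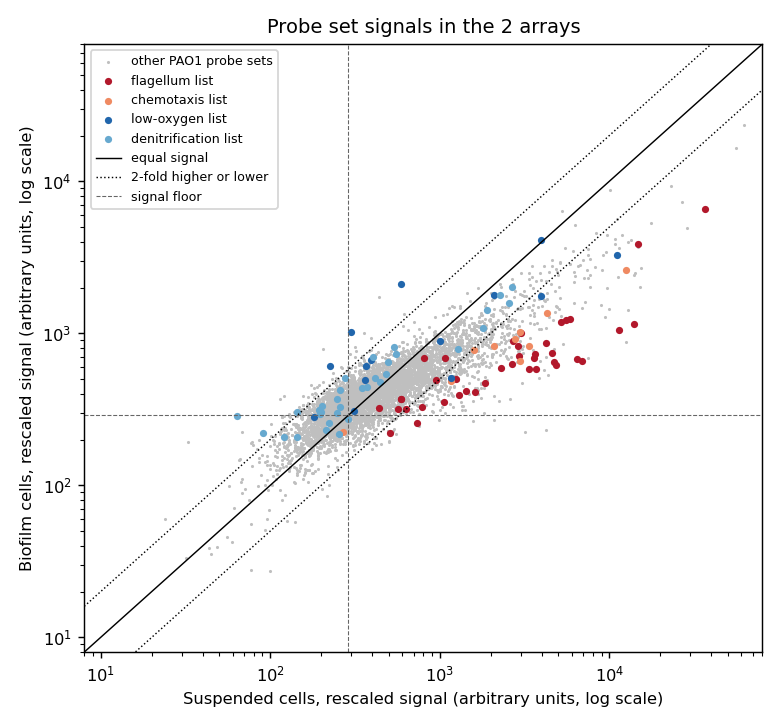
Rescaled signal of each PAO1 probe set (1 point each, arbitrary units, log scales) in suspended cells (x axis) and biofilm cells (y axis), with 4 gene lists coloured; the solid line marks equal signal, dotted lines 2-fold differences and dashed lines the floor of 289.3. Flagellar genes lie below the main cloud, and bright genes as a whole lie below the line of equal signal.

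Genes of the flagellum were lower in biofilm cells. All 38 measured members of the flagellum list had ratios below 0, 30 of them at least 2-fold lower (22 with loess centring and 21 with quantile normalization), and 2 further members were above the floor in 1 array only. The list's median log2 ratio was -1.98, below that of all 10000 random lists matched on signal, whose central 95% ran from -1.02 to -0.55. The 11 genes from flgB to flgL, which encode the rod, rings, hook and hook junction, ranged from -3.58 (flgE) to -1.98 (flgJ). The flagellin gene fliC (PA1092) had a signal of 32438 in suspended cells and 7387 in biofilm cells, a ratio of -2.47. The GTPase gene flhF was at -2.63, the motor switch genes fliG and fliM at -2.18 and -2.09, and the flagellar sigma factor gene fliA at -1.59. The smallest differences were in fleQ (-0.23), the master regulator gene of the flagellar cascade, and flhB (-0.43). The median remained negative in every alternative, from -2.47 to -1.16, the latter with loess centring, under which fleQ was at 0.23 and fliC at -0.55.

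Chemotaxis genes were lower as well. All 9 measured members were at least 2-fold lower, with a median of -1.60, but only PA1458 and pctA, 2 of the 9, were so with loess centring or with quantile normalization. The lowest were PA1464, a CheW-type coupling protein gene (-2.25), the amino acid receptor gene pctA (-2.16) and PA1458, a CheA-type kinase gene (-2.04). The response regulator gene cheY was at -1.35. This list lay at the 2.10th percentile of random lists and at 3.12 with trimmed-mean scaling and 2.88 with the floor at the 50th percentile, which ends its standing apart. Its median with quantile normalization was -0.61.

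Genes of the tricarboxylic acid cycle and glyoxylate shunt, the central route of carbon oxidation, were lower in biofilm cells. Of 18 members, 17 had ratios below 0 and 8 were at least 2-fold lower, of which 1, acnA, was so with loess centring or with quantile normalization. The isocitrate dehydrogenase gene icd was at -1.65, the aconitase gene acnA at -1.58, the succinyl-CoA synthetase gene sucC at -1.52 and the isocitrate lyase gene aceA at -1.50. The exception was mqoB, at 0.47. The median of -0.94 lay at the 0.14th percentile of random lists, and the list stood apart in each of 14 alternatives, with medians from -1.35 to -0.53.

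The psl operon, which makes a matrix exopolysaccharide, was also lower. Its 13 measured genes had a median of -0.92, 5 of them at least 2-fold lower (0 with loess centring or quantile normalization), led by pslD (-1.51), pslE (-1.51) and pslB (-1.42), with pslK at 0.42. The list lay at the 2.30th percentile of random lists. It did not stand apart with loess centring (3.36, or 5.52 with neighbouring genes also kept together in the random lists), with the floor at the 50th percentile (3.54) or after subtraction of intergenic signal (3.56).

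Genes of low-oxygen metabolism lay above random lists of the same signal. Of 12 measured members on the rescaled values, 2 were at least 2-fold higher, PA3309 (1.83) and adhA (1.76), and 3 at least 2-fold lower, the azurin gene azu (-1.77), the oxygen-sensing regulator gene anr (-1.20) and the ornithine carbamoyltransferase gene arcB (-1.17). None of the 12 was at least 2-fold lower with loess centring or quantile normalization: azu was at -0.20 and -0.15, anr at -0.72 and -0.77, and arcB at 0.024 and 0.15. The genes of a high-affinity cytochrome oxidase, ccoP2, ccoO2 and ccoN2, were at 0.76, 0.74 and 0.44. The arginine deiminase gene arcA was at 0.06, and at 1.45 with loess centring. With loess centring 3 members, PA3309, adhA and arcA, were at least 2-fold higher. The list median was 0.02 at the 99.9th percentile, and its value ran from -0.23 with the floor at the 50th percentile and -0.02 after subtraction of intergenic signal to 0.28 as deposited, 0.63 with loess centring and 0.72 with quantile normalization. It lay at the 90.2nd percentile of lists not matched on signal and at the 81.3rd of random lists that keep neighbouring genes together, against the 99.98th of the latter after loess centring.

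Denitrification genes, which reduce nitrate stepwise to dinitrogen, did not share the lower ratios of genes of like signal. None of the 15 measured members was 2-fold apart (2, nirM and narI, were 2-fold higher with quantile normalization), 9 had ratios above 0, and the median was 0.16 at the 99.97th percentile of random lists. Of the other members, 10 were above the floor in 1 array only, all in the biofilm array, and 8 below it in both. The bounds of those 10 ran from 0.02 (PA0513) to 0.81 (nirJ). With the bounds of those 10 included the median was also 0.16. The cytochrome gene nirM was at 0.79, the membrane nitrate reductase gene narI at 0.61 and the nitrous oxide reductase gene nosZ at 0.25. The periplasmic nitrate reductase genes napA to napF ran from -0.73 (napC) and -0.70 (napA) to -0.34 (napF) on the rescaled values, and all but napB (-0.034) were above 0 with loess centring, up to 0.73 (napD and napF). With neighbouring genes kept together in the random lists the percentile was 95.3, inside the central 95%, and 98.4 after loess centring, outside it.

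Another 5 lists lay above random lists without a member 2-fold higher on the rescaled values. With loess centring, and also with quantile normalization, 2 quorum-sensing products, 2 phenazine genes and 1 adhesin gene were at least 2-fold higher. The 5 lists were the siderophore pyochelin (median 0.39, 99.8th percentile, 7 of 7 genes above 0), the Cup and Cdr adhesins (0.32, 99.5, 4 measured), quorum-sensing products (0.18, 99.5), the Pf filamentous prophage (0.36, 99.3) and phenazine synthesis (0.25, 98.5). The 7 pyochelin genes had rescaled suspended signals close above the floor, from 291.5 (pchC) to 353.5 (pchA). Measured genes also had to be above the floor in biofilm cells, so ratios far below 0 were not possible for them. Their shared sign therefore carries little information on direction. A further 8 adhesin genes were above the floor in 1 array only, and with their bounds included the adhesin median was 0.11. Examples were pchC, pchG and pchB at 0.75, 0.73 and 0.59, cupA5, PA4625 and cupB4 at 0.56, 0.37 and 0.27, and PA0727, PA0722 and PA0717 of the prophage at 0.57, 0.52 and 0.52. The phenazine genes phzE2, phzF2 and phzG2, uncertain as above, were at 0.80, 0.32 and 0.27. Among quorum-sensing products the elastase gene lasB was at -1.91, rhlC at -0.75 and cbpD at -0.54, while the lectin genes lecA and lecB were at 0.30 and 0.26. With loess centring lasB was at -0.95, and lecA and lecB at 1.17 and 1.81. None of these lists stood apart when random lists kept neighbouring genes together, on the rescaled values (percentiles 97.49, 95.8, 95.6, 97.2 and 93.5 in the same order) or after loess centring. In all they stood above random lists in 9 of 11, 7 of 13, 6 of 14, 9 of 14 and 8 of 14 alternatives. Quorum-sensing products were at percentile 60.0 with quantile normalization and 81.9 with loess centring, with a median of -0.54 with the floor at the 50th percentile, and adhesins were at 62.6 to 63.9 with the other-strain floor, a pseudocount or no floor.

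**Figure D3:**
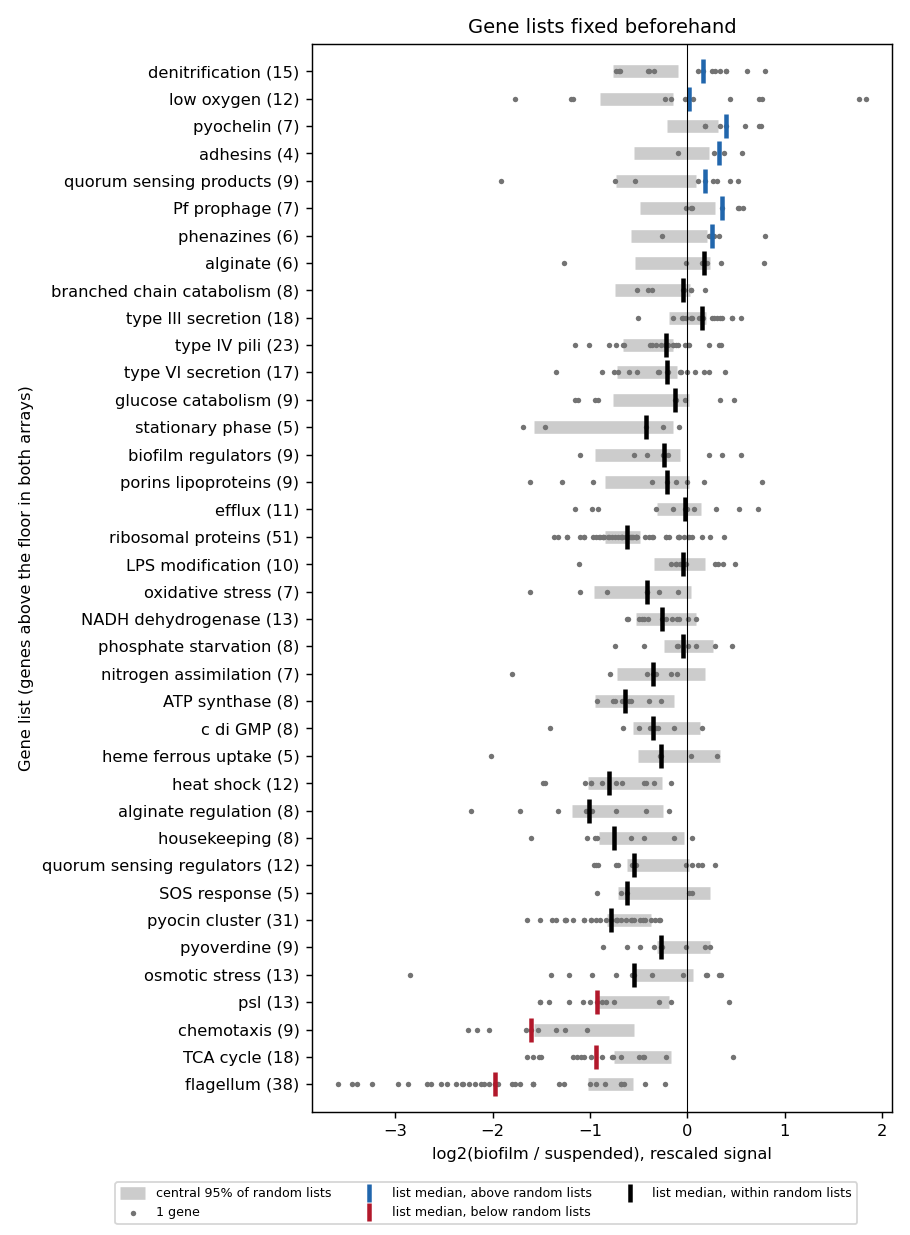
Log2 ratio of biofilm over suspended cells for each measured gene (grey points) of 38 gene lists, with the list median as a vertical mark and the central 95% of 10000 random lists matched on signal as a grey bar; the number of measured genes is in parentheses. The flagellum median of -1.98 lies farthest below its bar, and denitrification (0.16) and low oxygen (0.02) lie above theirs.

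The other 27 lists with a value lay within random lists of the same signal. Of these, 11 had a median of the same sign under each of 5 other scalings. Among them, the AlgU and Muc regulators of alginate were at -1.01, with mucA at -2.22, while alginate synthesis was at 0.17, with algC at -1.26. Heat shock was at -0.81 (groEL at -1.48), oxidative stress at -0.42 (ahpC at -1.62), osmotic stress at -0.54 (osmC at -1.40) and the DNA damage response at -0.62. The R- and F-type pyocin cluster was at -0.78, with 31 of 31 measured genes below 0 and 10 at least 2-fold lower, against 22 below 0 and 2 at least 2-fold lower with loess centring. ATP synthase was at -0.64, cyclic di-GMP turnover at -0.35 and nitrogen assimilation at -0.36 (glnA at -1.81). Type III secretion was at 0.15, and it stood above random lists in 9 of 14 alternatives. Osmotic stress and the pyocin cluster each stood below random lists in 5 of 14 alternatives, the regulators of alginate in 3 and heat shock in 1, and the other 6 of these 11 lists stood apart in none.

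Of the 11 single genes given here as examples of lower signals in these 27 lists, only sodM was at least 2-fold lower with loess centring (-1.63), while rmf was at -0.051 and oprF at -0.23. These examples do not stand for all members. With loess centring osmE of the osmotic stress list was at -1.90, and 2 pyocin cluster genes were at least 2-fold lower. The type IV pilus gene pilA, above the floor in suspended cells only, had a bound of -2.83. For 16 of the 27 lists the sign of the median depended on the scaling. Ribosomal proteins had a median of -0.62 over 51 genes (7 at least 2-fold lower, 0 with loess centring), which was 0.22 with quantile normalization and 0.17 with loess centring. Their percentile was 60.4 on the rescaled values and 98.8 with loess centring. It was 1.71 among random lists that keep neighbouring genes together and 0 among lists only left unmatched on signal. Stationary phase (-0.43, with rmf at -1.69) and quorum-sensing regulators (-0.55) were also positive with quantile normalization and loess centring, and genes used as expression references (-0.75) with quantile normalization alone. Positive as deposited and with trimmed-mean scaling were NADH dehydrogenase (-0.26), efflux pumps (-0.02, with mexB at -1.15), heme and ferrous iron uptake (-0.27, with the manganese superoxide dismutase gene sodM at -2.02), phosphate starvation (-0.04), porins and lipoproteins (-0.21, with oprF at -1.62) and pyoverdine (-0.27). Positive under all 4 of these scalings were type IV pili (-0.22), type VI secretion (-0.21), biofilm regulators (-0.24), lipopolysaccharide modification (-0.05) and branched-chain catabolism (-0.04). Glucose catabolism (-0.13, with gcd at -1.15) was positive under 3 of them, all but the trimmed mean. Of the lists whose sign depended on the scaling, pyoverdine stood below random lists in 5 of 14 alternatives, ribosomal proteins in 2 and the expression references in 1. Biofilm regulators stood above in 3, lipopolysaccharide modification and branched-chain catabolism in 2 each, and type VI secretion and ribosomal proteins in 1 each. Of the pel exopolysaccharide locus only 2 of 7 genes were measured, pelF at 0.59 and pelD at -0.034. In all, 7 lists lay above and 4 below random lists. By chance 1.9 of 38 would be outside if members of a list were as independent as randomly drawn genes. Ratios of adjacent loci correlated with r = 0.45, so this condition is not met for lists of neighbouring genes. With random lists that keep neighbouring genes together, which were not matched on signal and often held fewer measured genes, 0 lay above. How much of this loss is due to the smaller lists was not tested. Dropping the matching on signal alone ended the standing apart of 1 list, low oxygen (percentile 90.2). In a simulated pair of arrays 4 of 38 lists that had not been shifted as a whole stood apart. That pair had changes planted in single bright genes, which could be list members. It had no planted correlation of neighbours or trend with signal, so it gives no chance rate for the real arrays.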

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

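The tests of unspecific background, of the count of flagellar and chemotaxis genes, of the low-oxygen list and of the neighbours of its members were chosen after the result they bear on had been seen, and each pattern rests on 1 array per group. A signal outside the genes compared above was seen in intergenic probe sets: 194 of 199 lay above the 95th percentile of other-strain probe sets in both arrays. Their median was 54.0% of the PAO1 gene median in suspended cells and 55.3% in biofilm cells. The tRNA probe sets were also set aside, and 13 of 18 were higher in biofilm cells on the rescaled values, with a median log2 ratio of 0.41, and 16 of 18 on the values as deposited, with a median of 0.74.

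The first pattern is the narrower range of signals in the biofilm array. Background left in the deposited values of all biofilm probe sets is argued against by the other-strain probe sets. Their median log2 ratio on the deposited scale was -0.77 (95% bootstrap interval over 117 probe sets -1.10 to -0.48). The background correction is not known, so background removed before deposit cannot be seen this way. Saturation of bright probe sets as the cause of the narrower range is argued against by the slope of the log2 ratio on mean log2 signal. That slope was -0.18 (-0.28 to -0.09) among the brightest 5% of genes and steeper, -0.56 (-0.61 to -0.52), between the 50th and 95th percentile. A ceiling met only by the very brightest signals, such as those of rRNA, was not tested. A strand-independent signal such as labelled genomic DNA, added in the biofilm array, would make the strands of an intergenic region more alike there. The median absolute log2 strand ratio over 99 regions was 0.59 against 0.61, a difference of -0.014 (-0.16 to 0.22). Adding 300 units to the suspended array's intergenic signals in a simulation gave -0.42, with an interval ending at -0.28. The observed interval lies above that, but 300 units exceed the median intergenic signal of the biofilm array, 248.6 as deposited. The simulation therefore does not bear on additions of a size that these signals could hold. A smaller addition and its absence cannot be told apart. A real flattening of the transcriptome in attached cells also stays open, as untested.

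The second pattern is the lower flagellar and chemotaxis signals. The narrower range alone is argued against for the flagellum, because after loess centring, which removes the trend with signal, its median of -1.16 lay at percentile 0 of random lists (central 95% -0.22 to 0.17) and 22 of 38 genes were still at least 2-fold lower. Random error of single probe sets is argued against as the whole cause by all measured members of the 2 lists, fixed beforehand: 46 of 47 had ratios below 0 after loess centring, against at most 37 in 10000 random sets of measured genes. Attachment to the membrane, and any other difference between these 2 harvests, stay open, because a second culture of either kind was not analysed here.

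The third pattern is the place of low-oxygen genes among the largest increases. Random error of dim probe sets stays open: the locus neighbours of the 39 genes at least 2-fold higher after loess centring lay at the 99.3rd percentile of random neighbour sets, but only 3 of those 39 genes are on the low-oxygen list, and the 6 neighbours of these 3 lay at the 89.6th percentile, too few to decide. Oxygen limitation in the biofilm is a candidate explanation, and the list fixed beforehand lay at the 99.9th percentile of random lists matched on signal. With neighbouring genes kept together and no matching on signal it lay at the 81.3rd percentile on the rescaled values. It lay at the 99.98th after loess centring, so the outcome depends on whether the trend with signal is removed. Oxygen limitation and other differences between these 2 arrays cannot be told apart, because oxygen was not among the measurements analysed here and each group has 1 array.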

How the results depend on the processing

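No paired analysis was possible because each group has 1 array, and leaving out a replicate was not possible for the same reason. The counts of genes 2-fold apart depend on the scaling: against 11 higher and 422 lower, they were 37 and 229 as deposited, 37 and 226 with trimmed-mean scaling, 61 and 109 with quantile normalization, 39 and 108 with loess centring, and 193 and 845 after subtraction of intergenic signal, the last chosen after seeing the data. A 4-fold threshold gave 0 and 63, and under other scalings, a combination chosen after seeing the data, from 0 to 3 higher and from 11 to 63 lower. The count of higher genes also moved with the floor, to 75 with none, 73 with the other-strain floor, 19 at the 10th percentile and 3 at the 50th, the last with fewer genes measured (2264). Random lists that kept neighbouring genes together left 0 lists above instead of 7, or 3 (low oxygen, denitrification and biofilm regulators) when loess centring was applied as well, a combination chosen after seeing the data. Those random lists were not matched on signal either, and they often held fewer measured genes than the list. Dropping the matching on signal alone gave 9 below instead of 4. In the other alternatives the counts of lists stayed within 1.5 times, and the flagellum and tricarboxylic acid cycle lists stood below random lists in each of 14 alternatives. Of the 27 lists that did not stand apart, 12 did so in at least 1 alternative. Of 143 named genes, 76 moved by over 1.5 times with loess centring, 71 with quantile normalization and 40 after subtraction of intergenic signal. These counts leave out 2-fold genes whose ratio changed sign, 1 with loess centring and 4 with quantile normalization. Among those counted as 2-fold lower, the ratio changed sign with quantile normalization for rsmA (0.036), rpoA (0.038), rpoS (0.19) and fimV (0.13), and with loess centring for rpoS (0.082). The further example arcB changed sign under both (0.15 and 0.024). The cause of these shifts was not tested beyond the trend of the ratio with signal. Signals near the floor carry little information on direction, and differences in total RNA cannot be seen in these scaled values.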

Other observations

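Genes next to each other on the chromosome had similar ratios. Across 2658 pairs of adjacent loci measured in both arrays the log2 ratios correlated with r = 0.45, against at most 0.06 in 1000 shuffles of the genes, and with r = 0.36 after loess centring. At a distance of 20 loci r was 0.06 and at 100 loci 0.01. These are correlations across genes of 1 pair of arrays, which are not independent replicates. Pairs of neighbours outside the gene lists, chosen after their values were seen, include PA1323 and PA1324 (-3.03 and -2.55), PA3421 and PA3422 (-2.63 and -2.61) and PA4738 and PA4739 (-2.80 and -2.11), all lower in biofilm cells.

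Some bright genes kept their signal in the biofilm array where genes of like signal were lower, also chosen after their values were seen. The lectin gene lecB had a deposited signal of 4706 in suspended and 7124 in biofilm cells, and its log2 ratio was 0.26 on the rescaled values and 1.81 with loess centring. The lectin gene lecA was at 0.30 and 1.17, the integration host factor gene himA at -0.22 and 1.52, and the glyceraldehyde-3-phosphate dehydrogenase gene gapA at 0.34 and 1.12.

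The 3 rRNA probe sets had a median deposited signal of 67938 in suspended cells and 34128 in biofilm cells. The highest intergenic signals were at like levels, 72074 and 33059, so whether rRNA itself differed cannot be told from these values. The spread of log2 signal over intergenic probe sets was an SD of 1.21 in suspended and 1.15 in biofilm cells, while over PAO1 genes it was 1.15 and 0.79.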
